A study of Homo sapiens with 7 samples.

How the data were processed

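Poly(A)-selected RNA of MOLM13 cells was sequenced in 7 libraries: 3 with the non-targeting guide sgRosa and 2 with each of 2 guides against ZFP36L2, taken 6 days after transduction. Per the labels' protocols, a directional library kit was used and sequencing was single-end on a HiSeq4000. Per the submitters' processing notes, STAR 2.5.3, HTSeq, edgeR and limma were used with GRCh38.p7 and hg38; the notes give no roles or parameters, and the strand setting of the counting is not stated. One of the authors' deposited tables holds FPKM, read counts scaled by gene length and library size, for each library. The authors' deposited table of differential expression holds log2 fold changes of each guide over control, a p-value and a false discovery rate from edgeR for each, and group means of CPM, counts scaled to an adjusted library size. It holds no comparison of both guides together with control.

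Both deposited tables list 11581 genes, of which 173 have no FPKM, symbol or type and were left out, leaving 11408. Dividing the mean CPM of a group by its mean FPKM gave a whole number of bases for all 11408 genes (within 0.01 bases), with a median of 30113.5 bases. These lengths equal the span from gene start to gene end in GENCODE 29 for 8064 genes and lie within 5% of it for 10382, so the authors' FPKM are per kilobase of the whole gene, introns included, and are low for long genes. Multiplying FPKM by this length gave whole reads (within 0.01) for 100% of values in each of the 7 libraries, from which the reads per library were recovered. A single read stood for 0.0261 to 0.0540 CPM. The reads carry no molecular identifiers, so depth limits cover counting error alone.

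The deposited columns name the ZFP36L2 guides 3 and 5, while the labels number them in another way, and nothing in the files pairs them. The names of the deposited columns are therefore kept, and no statement depends on the pairing. Columns named for Rosa were taken as the controls. No pair of libraries held the same values. Gene coordinates, transcript GC content and 3′ UTRs come from GENCODE 29, where all 11581 identifiers were found. On the same strand, CHML overlaps OPN3, HLA-C overlaps HLA-B, EPOR overlaps RGL3, and TIA1 overlaps C2orf42.

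Genes with FPKM of at least 1 in at least 2 libraries were tested, 6783 in all. Because the FPKM are per kilobase of gene span, this filter favors short genes. It also admits a gene near 0 FPKM in 1 arm only where the other arm is higher. The values log2(FPKM + 0.5) were fitted with limma 3.58.1 in R 4.3.3, with a mean for each of the 3 groups and moderated variances with a mean-variance trend (4 residual and 6.21 prior degrees of freedom). The comparisons were the mean of both guide groups minus control, each guide minus control, and guide 5 minus guide 3. All tests were two-sided, and p was adjusted by Benjamini-Hochberg over the tested genes with a threshold of 0.05. Of 30 gene lists, those with at least 5 tested members, 26 in all, were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists; camera with an estimated correlation and fry stand beside it. With an estimated correlation, camera rests on the 4 residual degrees of freedom, so its p is larger even where genes do not vary together. Rises and falls were also counted with p adjusted over the list alone. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9. The groups, tests, lists, alternatives and the rule for named genes were chosen before the data were examined, except where stated.

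The named genes are ZFP36L2 and its 2 paralogs; the 8 highest and the 8 lowest log2 changes among genes past the threshold with the same sign for both guides and no overlap between arms; up to 4 called members of each list, some of which are left out of the text; CD14, ITGAM and MYC; the 3 highest and 3 lowest for each guide; and the 4 highest and 4 lowest for the difference between guides. Agreement between guides was set against 100 simulations of unchanged groups that share the 3 controls, because 3 libraries cannot be split evenly. Each gene was drawn independently in them. The procedure was tested on simulated data with 6593 genes. Calls were made for 92.8% of 97 genes changed 2-fold and 100% of 96 genes changed 4-fold. Of 203 calls 17 were false, a larger share than the threshold on adjusted p aims for. Of 29 random lists 0 passed. Random lists are not made of genes that vary together, so they cannot show whether the preset correlation suits the real lists.

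Alternatives were other pseudocounts (0.1 and 1), no filter or a mean FPKM of at least 5, quantile, common sum and median of ratios scaling, the replicate number as a block, no variance trend, library weights, a single mean for both guides, fits of the compared groups alone, and each library left out in turn. Added after the data were examined were the recovered reads as CPM, limma voom on recovered reads, a correction for GC content and length, the counts of the authors' deposited table, a heat shock list, and the list tests of the guide difference, also without the members seen first. The correction fits natural splines with 5 degrees of freedom each for transcript GC content and length to the deviations of each library from the gene means. The test of AU-rich elements compared genes with and without the heptamer in an annotated 3′ UTR of at least 50 bases, permuting log2 changes within 20 bins of 3′ UTR length 100000 times. Mitochondrially encoded genes are absent from the tables and were not analysed here.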

Results

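RNA was measured in 7 libraries of MOLM13, a human acute myeloid leukemia cell line, harvested 6 days after transduction with guide RNAs. The 3 control libraries carried sgRosa, a non-targeting guide per the labels. The other 4 carried 1 of 2 guides against ZFP36L2, with 2 libraries per guide, called guide 3 and guide 5 here after the names in the deposited tables. The reads assigned to the listed genes, recovered from the deposited values, came to 16907955, 25164359 and 22631858 in control replicates 1 to 3. They came to 33735298 and 38807816 with guide 3 and to 36556997 and 28088053 with guide 5. Values below are FPKM as deposited, given as mean ± SD, and log2 changes of FPKM + 0.5, given as estimate ± SE. The labels do not say whether replicates were separate cultures, so the p-values measure the spread between these samples alone.

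ZFP36L2, the targeted gene, encodes an RNA-binding protein that binds AU-rich elements in 3′ UTRs and promotes mRNA decay. Its mRNA was higher in the libraries labelled knockout, at 232 ± 76.0 FPKM (SD, n = 4) against 77.8 ± 3.42 FPKM (SD, n = 3) in controls, a log2 change of 1.51 ± 0.16 (adjusted p = 8.2e-05). Each of the 4 libraries lay above each control: 269 and 322 FPKM with guide 3, 174 and 164 FPKM with guide 5. Small insertions and deletions left by genome editing need not lower an mRNA, so its level neither shows nor excludes loss of the protein, and every direction below is that of the libraries labelled knockout. The gene (ENSG00000152518) lies on chromosome 2, 43222402 to 43226609, in GRCh38. Both paralogs rose as well. ZFP36 went from 35.3 ± 8.61 to 93.4 ± 14.0 FPKM (SD, n = 3 and n = 4), a log2 change of 1.41 ± 0.19 (adjusted p = 0.00043). ZFP36L1 was close to 0 in controls at 0.0511 ± 0.0431 FPKM and reached 1.06 ± 0.103 FPKM (SD, n = 3 and n = 4), with a log2 change of 1.50 ± 0.10 (adjusted p = 2.9e-06).

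**Figure D1:**
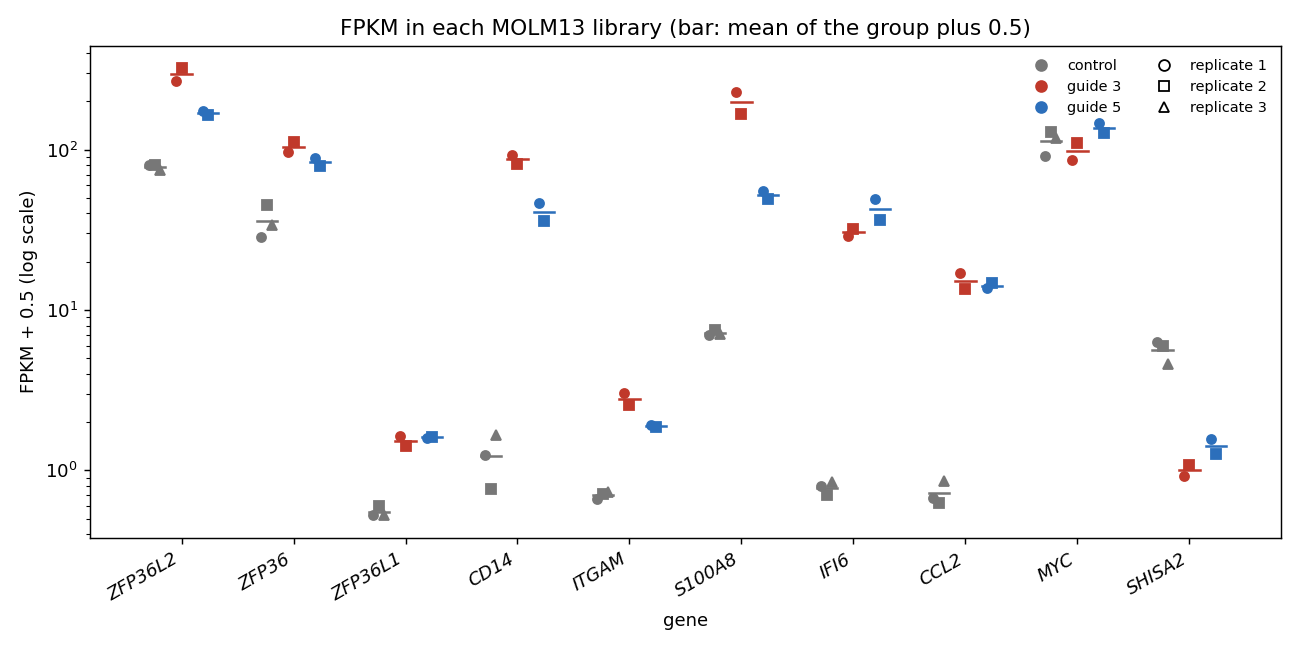
FPKM + 0.5 per library (vertical log axis) of named genes (horizontal axis) in the controls and with each guide; each point is 1 library and each bar is a group mean plus 0.5. As FPKM, ZFP36L2 lies between 73.9 and 80.2 FPKM in the controls and between 164 and 322 FPKM in the libraries labelled knockout.

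The comparison of the 4 labelled-knockout libraries with the 3 controls asks how mRNA levels of these leukemia cells change when ZFP36L2 is targeted, with genes of myeloid differentiation as the subject of the series title. CD14, a monocyte surface receptor for lipopolysaccharide, had the largest rise on the scale of log2(FPKM + 0.5), from 0.720 ± 0.451 to 63.5 ± 27.2 FPKM (SD, n = 3 and n = 4), a log2 change of 5.68 ± 0.24 (adjusted p = 1.7e-07). The interferon-induced gene IFI6 followed with 5.53 ± 0.16 (adjusted p = 4.8e-08) and the monocyte-attracting chemokine CCL2 with 4.37 ± 0.16 (adjusted p = 9.1e-08). Next came the monocyte lectin FCN1 (4.28), the macrophage adhesion receptor SIGLEC1 (4.15) and the calcium-binding proteins S100A8 (3.81), S100A12 (3.79) and S100A9 (3.77). SHISA2, which encodes a membrane protein of the endoplasmic reticulum, had the largest fall, from 5.11 ± 0.916 to 0.711 ± 0.282 FPKM (SD, n = 3 and n = 4), a log2 change of -2.23 ± 0.16 (adjusted p = 4.1e-06).

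The other 7 genes with the largest falls had log2 changes of -1.59 for CHML, a Rab escort protein, -1.58 for IGSF10, -1.53 for the pseudogene EIF4BP7, -1.47 for the co-chaperone BAG2, -1.44 for the metallothionein MT1H, -1.41 for the cell division gene CDCA7 and -1.39 for the T cell receptor constant segment TRDC. CHML shares exons on the same strand with OPN3, and EIF4BP7 and MT1H have close copies elsewhere, so their reads need not come from these genes alone. By the rule for naming them, these highest and lowest genes moved the same way with both guides and did not overlap between arms. CD14 (ENSG00000170458) lies on chromosome 5, 140631728 to 140633701, IFI6 (ENSG00000126709) on chromosome 1, 27666061 to 27672218, and SHISA2 (ENSG00000180730) on chromosome 13, 26044597 to 26051031. For genes near 0 FPKM in controls, such as FCN1 at 0.0850 ± 0.0280 FPKM (SD, n = 3), the size of the log2 change depends on the added 0.5. It makes changes smaller for other genes of low FPKM too, which long genes tend to have, and so can affect list medians. HLA-DRB1 had a log2 change of 1.42 here, against 4.07 with guide 3 and 3.44 with guide 5 in the authors' deposited table. The order of the rises also changes with the measure: IFI6 stood above CD14 with 0.1 added, and SIGLEC1, IFI6, IFI27 and FCN1 did with recovered CPM. In the authors' deposited table the log2 fold changes of S100A12 (8.77), FCN1 (7.78), SIGLEC1 (7.26) and IFI27 (7.12) were above CD14 (6.89) with guide 3, and IFI27 (7.59), SIGLEC1 (7.44) and IFI6 (7.23), among others, above CD14 (5.80) with guide 5.

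Of 6783 tested genes, 1526 rose and 1339 fell. The shares in each direction depend on the scaling of the libraries: 1356 rose and 1930 fell with quantile normalization, 1141 and 2371 with every library scaled to the same sum of FPKM, and 1228 and 1716 after correction for GC content and length. Scaling to the same sum moved the median change of all genes to -0.20, so changes are relative to a typical gene. Over the 2347 genes with mean FPKM of at least 5 the median change was 0.11. Changes also followed the GC content of the transcripts: in the tenth of genes with the least GC, 2.95% rose and 52.0% fell, and in the tenth with the most, 56.1% rose and 0% fell. The 3 controls differed along the same axis, and control replicate 2 stood apart from the rest, with 0.160% of reads in mitochondrial pseudogenes against 0.0463% to 0.0828% in the other 6 libraries. Without control replicate 2, 1839 genes rose and 1266 fell. Without guide 3 replicate 2, 966 rose and 563 fell, and without guide 5 replicate 1, 977 rose and 559 fell; without control replicate 1 and without guide 3 replicate 1, 862 and 818 fell. Because of this trend, each of the 26 lists tested below is given with its median after correction of each library for GC content and transcript length, called the GC-corrected median and chosen after the data were examined. Counts and medians of the lists cover tested members alone. A member near 0 FPKM in controls is tested only if the guide libraries are higher, so the filter can raise the share of rises and the medians. With no filter on low values 14 lists were higher and 5 lower by camera, against 13 and 4 with it.

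**Figure D2:**
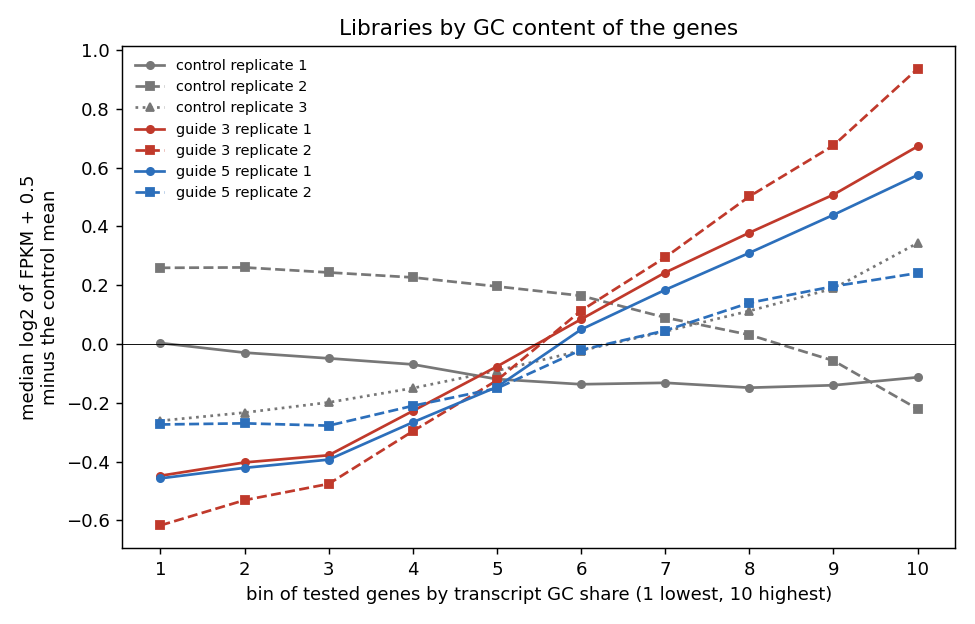
Median log2 of FPKM + 0.5 minus the control mean (vertical axis) in 10 bins of tested genes ordered by the GC content of their transcripts (horizontal axis); each line is 1 library. The highest bin minus the lowest bin is -0.48 to 0.60 on the log2 scale among the 3 controls and 0.52 to 1.55 among the 4 libraries labelled knockout.

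Genes of monocyte and macrophage differentiation rose together: 28 of 32 tested members rose and 0 fell, with 4 not past the threshold (29 risen and 0 fallen adjusted over the list alone). The median log2 change was 1.44 (GC-corrected 1.29), with adjusted p = 3.4e-15 by camera and adjusted p = 0.12 with an estimated correlation. Besides CD14, FCN1, S100A8 and S100A12, the integrin ITGAM, the CD11b chain of myeloid cells, rose by 1.71 ± 0.11 on the log2 scale (adjusted p = 2.1e-06). Mature granulocyte genes moved the same way, with 11 of 12 risen and 0 fallen (11 risen and 0 fallen adjusted over the list alone), a median of 1.61 (GC-corrected 1.17), camera adjusted p = 3.2e-07 and adjusted p = 0.19 with an estimated correlation. Among them were NCF1 (2.83) and CYBB (2.19), subunits of the phagocyte oxidase, the activating receptor TREM1 (2.54) and the gelatinase MMP9 (2.29). NCF1 has near-identical copies, so its reads could be shared among them. Genes of promyelocyte primary granules did not move as a group: 4 of 14 rose and 2 fell (4 risen and 2 fallen adjusted over the list alone), with a median of 0.33 (GC-corrected 0.09) and camera adjusted p = 0.28. Neutrophil elastase, ELANE, rose by 1.45 and myeloperoxidase, MPO, fell (-0.74). The myeloid transcription factor CEBPA (1.04) and the granule protein AZU1 (0.89) also rose, yet their adjusted p was 0.11 and 0.18 after GC correction, and that of AZU1 reached 0.066 without guide 5 replicate 1. Without control replicate 2, 7 members of this list rose and 2 fell, and after GC correction 4 rose and 5 fell.

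All 27 tested interferon-stimulated genes, of 38 listed, rose, with a median log2 change of 2.03 (GC-corrected 2.01, 27 risen and 0 fallen adjusted over the list alone). The list had camera adjusted p = 2.2e-19 and adjusted p = 0.12 with an estimated correlation. IFI6 was followed by the antiviral proteins IFIT2 (3.66 ± 0.17, adjusted p = 2.4e-07) and IFIT3 (3.52) and by IFI27 (3.62), from 0.0386 ± 0.0312 to 6.24 ± 1.57 FPKM (SD, n = 3 and n = 4). Antigen presentation genes rose in 15 of 17 cases and fell in 0 (15 risen and 0 fallen adjusted over the list alone). Their median was 0.82 (GC-corrected 0.75), with camera adjusted p = 2.3e-06 and adjusted p = 0.21 with an estimated correlation. HLA-DRA (2.25) and HLA-DRB1 (1.42) encode class II chains, and HLA-C (1.72) a class I chain; reads of HLA genes are hard to assign to 1 member.

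Inflammatory mRNAs known for AU-rich elements, the kind that ZFP36 family proteins bind, rose in 14 of 17 tested cases and fell in 0 (15 risen and 0 fallen adjusted over the list alone). Their median was 1.61 (GC-corrected 1.24), with camera adjusted p = 4.9e-09 and adjusted p = 0.12 with an estimated correlation. Beside CCL2 stood the cytokine IL1B (3.34 ± 0.18, adjusted p = 5.9e-07), the anticoagulant receptor THBD (2.57) and the kinase PIM3 (1.98). Immediate early genes rose in 15 of 19 cases and fell in 0 (15 risen and 0 fallen adjusted over the list alone), with a median of 0.76 (GC-corrected 0.62), camera adjusted p = 9.6e-07 and adjusted p = 0.21 with an estimated correlation. The transcription factors KLF2 (2.89), JUN (2.44) and JUNB (1.75) and the antiproliferative gene BTG2 (1.96) led this list. In the NF-kappa-B list 10 of 16 members rose and 0 fell (12 risen and 0 fallen adjusted over the list alone), with a median of 0.52 (GC-corrected 0.23), camera adjusted p = 0.00019 and adjusted p = 0.22 with an estimated correlation. Its largest rises were TNFAIP2 (1.74), BCL3 (1.73), the adhesion molecule ICAM1 (1.61) and the survival factor BCL2A1 (1.60). Among chemokine and cytokine receptors 12 of 21 rose and 2 fell (12 risen and 2 fallen adjusted over the list alone), with a median of 0.68 (GC-corrected 0.62), camera adjusted p = 6.7e-05 and adjusted p = 0.37 with an estimated correlation. The chemokine receptor CCR1 (2.21), the interleukin receptor chain IL10RA (2.06) and the macrophage growth factor receptor CSF1R (1.81) rose, while FLT3 (-0.71) and IL6R (-0.51) fell.

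Lysosomal genes of phagocytes rose in 16 of 24 cases and fell in 0 (18 risen and 1 fallen adjusted over the list alone), among them GRN, from 53.3 ± 13.8 to 253 ± 62.5 FPKM (SD, n = 3 and n = 4). The cathepsins CTSD (2.33) and CTSB (1.97) and the sphingolipid activator precursor PSAP (2.27) rose too. The list's median was 0.76 (GC-corrected 0.67), with camera adjusted p = 3.2e-07 and adjusted p = 0.22 with an estimated correlation. In the NADPH oxidase and oxidative burst list 10 of 14 rose and 2 fell (10 risen and 2 fallen adjusted over the list alone), with a median of 0.90 (GC-corrected 0.67), camera adjusted p = 0.00050 and adjusted p = 0.22 with an estimated correlation. The oxidase subunits NCF1 and CYBB and the peroxide-reducing GPX1 (1.55) rose, and the antioxidant genes CAT (-0.68) and GCLM (-0.51) fell; the adjusted p of GCLM was 0.47 after GC correction. Glycolysis and hypoxia genes rose in 9 of 17 cases and fell in 0 (13 risen and 0 fallen adjusted over the list alone), with a median of 0.54 (GC-corrected 0.23), camera adjusted p = 0.00018 and adjusted p = 0.22 with an estimated correlation. The aldolase ALDOC (2.21), the hypoxia-induced gene NDRG1 (1.70), the glucose transporter SLC2A3 (1.05) and the hexokinase HK2 (0.67) had its largest changes.

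Genes of the unfolded protein and integrated stress response went both ways. In all, 13 of 22 rose and 3 fell (15 risen and 4 fallen adjusted over the list alone), with a median of 0.65 (GC-corrected 0.62), camera adjusted p = 0.00026 and adjusted p = 0.12 with an estimated correlation. The largest rises in the list were those of NUPR1 at 3.41, the mTORC1 inhibitor DDIT4 at 2.56, the glutathione-degrading CHAC1 at 2.46 and the secreted glycoprotein STC2 at 1.68. The 3 members that fell were the endoplasmic reticulum chaperones HSPA5 (-0.43) and HSP90B1 (-0.77) and the transcription factor XBP1 (-0.52), named after their values were seen; after GC correction the adjusted p of HSPA5 was 0.16. Targets of p53 went both ways, with 8 of 21 risen and 6 fallen (8 risen and 8 fallen adjusted over the list alone) and camera adjusted p = 0.90; the median was -0.13 (GC-corrected -0.21), the mean 0.20 and the test's direction upward. After GC correction 5 rose and 9 fell. The fry test called this list upward (adjusted p = 0.0025). The cell cycle inhibitor CDKN1A rose by 2.27 and SESN2 by 1.36, while CCNG1 fell (-0.91). Apoptosis regulators did not pass as a list: 7 of 16 rose and 3 fell (8 risen and 3 fallen adjusted over the list alone), with a median of 0.32 (GC-corrected 0.18) and camera adjusted p = 0.21. BCL2A1 and the death-promoting BMF (0.86) rose and the apoptosome protein APAF1 fell (-0.64). BAX (0.74) rose as well, with an adjusted p of 0.34 after GC correction and of 0.089 without guide 5 replicate 1.

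S phase genes fell: 16 of 26 tested members fell and 1 rose (1 risen and 16 fallen adjusted over the list alone), with a median of -0.52 (GC-corrected -0.51). The replicative helicase subunits MCM6 (-0.98 ± 0.15, adjusted p = 0.00084) and MCM4 (-0.92) and the origin factor MCM10 (-0.81) were among those that fell. The exception was E2F1 (0.47), a transcription factor that activates S phase genes, with -0.14 after GC correction (adjusted p = 0.35); without control replicate 2, 0 members of this list rose. The list's camera adjusted p was 1.5e-05, with adjusted p = 0.24 with an estimated correlation. Of the G2 and M phase genes, 12 of 27 fell and 0 rose (0 risen and 12 fallen adjusted over the list alone), with a median of -0.45 (GC-corrected -0.23), camera adjusted p = 0.0015, adjusted p = 0.51 with an estimated correlation and adjusted p = 0.092 by fry. The mitotic kinase TTK (-0.82), cyclin CCNA2 (-0.77), CENPF (-0.77) and topoisomerase TOP2A (-0.76) led; TOP2A reached an adjusted p of 0.056 without guide 5 replicate 1. Without control replicate 2, 2 members of this list rose and 10 fell. Genes of MYC response and ribosome biogenesis fell in 15 of 32 cases and rose in 0 (0 risen and 18 fallen adjusted over the list alone), with a median of -0.45 (GC-corrected -0.56), camera adjusted p = 0.00016 and adjusted p = 0.38 with an estimated correlation. The mitochondrial chaperone HSPD1 (-1.06) and the nucleolar genes NOP58 (-0.88), UTP20 (-0.84) and GNL3 (-0.78) led. After GC correction 26 members of this list fell and 0 rose. MYC itself was at 112 ± 19.7 FPKM in controls and 117 ± 25.2 FPKM in the other arm (SD, n = 3 and n = 4), a log2 change of 0.05 ± 0.19 (adjusted p = 0.85).

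Targets of MLL fusion proteins, which MOLM13 carries as MLL-AF9, fell in 10 of 16 cases and rose in 0 (0 risen and 11 fallen adjusted over the list alone), with a median of -0.54 (GC-corrected -0.31), camera adjusted p = 0.0019 and adjusted p = 0.42 with an estimated correlation. HOXA5 (-0.71) and the receptor kinase FLT3 (-0.71) fell, as did JMJD1C (-0.66) and SENP6 (-0.66). The stem and progenitor list did not pass: 1 of 9 rose and 4 fell (1 risen and 5 fallen adjusted over the list alone), with a median of -0.40 (GC-corrected -0.38) and camera adjusted p = 0.069. NPM1 (-0.73) and the transcription factor MYB (-0.66) fell, and the transcription factor LYL1 rose (1.06). After GC correction the adjusted p was 0.063 for LYL1 and 0.057 for SENP6. With 1 library left out it reached 0.073 for SENP6 (without guide 3 replicate 2), 0.089 for MYB (without guide 5 replicate 1) and 0.055 for JMJD1C (without guide 5 replicate 1).

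The CCR4-NOT and deadenylation list, the machinery that ZFP36 family proteins recruit, did not pass, with 2 of 23 risen and 6 fallen (2 risen and 6 fallen adjusted over the list alone), a median of -0.24 (GC-corrected -0.08) and camera adjusted p = 0.090. BTG1, which binds the deadenylase subunits, rose (0.78), while the AU-rich element binding proteins HNRNPD (-0.73) and TIA1 (-0.63) and the deadenylase CNOT7 (-0.70) fell. The adjusted p of CNOT7 was 0.056 after GC correction and 0.076 without guide 3 replicate 2. Without control replicate 2, 4 members rose and 5 fell. Cholesterol biosynthesis genes showed 3 rises and 5 falls among 19 (3 risen and 5 fallen adjusted over the list alone), with a median of 0.03 (GC-corrected -0.17) but a mean of -0.04 and a downward camera test (adjusted p = 0.51); after GC correction 2 rose and 3 fell. Among the rises was MVD (0.73), with an adjusted p of 0.97 after GC correction and of 0.063 without guide 5 replicate 1. Oxidative phosphorylation genes gave 3 rises and 1 fall among 22 (0 risen and 0 fallen adjusted over the list alone), with a median of 0.10 (GC-corrected 0.09) and camera adjusted p = 0.52. Among these calls were CYC1 (0.63), UQCRC1 (0.50) and ATP5F1 (-0.43), and each passed the threshold no longer with some library left out, at adjusted p of 0.094, 0.14 and 0.19. After GC correction CYC1 was at 0.01 (adjusted p = 0.97), UQCRC1 turned to -0.01 (adjusted p = 0.95) and ATP5F1 was at -0.15 (adjusted p = 0.41). Without control replicate 2 the list had 4 rises and 4 falls.

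Cytosolic ribosomal protein genes gave 1 rise and 4 falls among 24 (0 risen and 4 fallen adjusted over the list alone), with a median of 0.01 (GC-corrected -0.20), a mean of -0.05 and a downward camera test (adjusted p = 0.37). RPL27A (-0.64), RPL5 (-0.62) and RPS24 (-0.52) fell and RPS2 rose (0.51), but with 1 library left out their adjusted p reached 0.058, 0.099, 0.098 and 0.14, and RPS2 turned to -0.16 after GC correction (adjusted p = 0.40). Many pseudogenes resemble these genes. Without control replicate 2 the list had 2 rises and 7 falls. Replication-dependent histone mRNAs, which normally lack a poly(A) tail, were listed beforehand as a possible sign of RNA quality and selection. They rose in 3 of 5 cases and fell in 0 (4 risen and 0 fallen adjusted over the list alone). Their median was 1.36 (GC-corrected 1.36), with camera adjusted p = 0.0015 and adjusted p = 0.21 with an estimated correlation. HIST2H2BE (2.03), HIST1H1C (1.89) and HIST1H2AC (1.36) rose together with the monocyte, interferon and stress lists. Whether RNA quality, selection or a change of the cells lies behind this rise was not tested. No mitochondrially encoded gene is in the deposited tables, with 0 of 13 listed members.

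Markers of other cell types were mostly below the filter. Of 25 lymphoid markers 4 were tested: NKG7 (1.56), CD4 (0.75) and IL7R (0.69) rose and CD3D fell (-0.96), with a median of 0.72 (GC-corrected 0.75). Of 22 erythroid and megakaryocyte markers 2 were tested: the erythropoietin receptor EPOR rose (0.68), and the transferrin receptor TFRC fell (-0.47), with an adjusted p of 0.62 after GC correction and 0.16 without guide 5 replicate 1; their median was 0.10 (GC-corrected 0.06). The only epithelial and fibroblast marker tested of 14 was VIM, which monocytes also express, and it rose (0.95, GC-corrected 0.70). Dendritic cell markers rose in 2 of 5 tested cases and fell in 1 (4 risen and 1 fallen adjusted over the list alone), with a median of 0.31 (GC-corrected 0.40) and camera adjusted p = 0.082. The lectins CD209 (1.99) and CLEC10A (1.84), which macrophages can also express, rose, and FLT3 fell; without control replicate 2, 4 rose and 1 fell. These rises stood beside those of the monocyte and antigen presentation lists.

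Over the 26 lists with at least 5 tested members, 13 ranked higher and 4 lower than other genes by camera with the preset correlation. With an estimated correlation, a setting that rests on the 4 residual degrees of freedom, 0 lists passed. At an unadjusted p under 0.05 that setting gave 5 higher and 0 lower. Fry, which does not compare a list with other genes, called 16 upward and 4 downward. Of the 4 lists lower by camera, fry did not call G2 and M phase (adjusted p = 0.092), and it called the stem and progenitor list (adjusted p = 0.027) in addition. Upward, fry also called the p53 (adjusted p = 0.0025), apoptosis (0.0063) and dendritic cell (0.0013) lists. With genes of mean FPKM of at least 5 alone, 5 of the camera calls ended: MLL fusion targets (adjusted p = 0.23), G2 and M phase (0.070), NF-kappa-B (0.12), NADPH oxidase (0.076) and the unfolded protein and integrated stress response (0.35), while cholesterol biosynthesis passed (0.015). In that setting 23 lists had at least 5 tested members, with 8 higher and 3 lower, so some called lists were no longer tested. After GC correction the stem and progenitor (adjusted p = 0.049), dendritic cell (0.043) and apoptosis (0.016) lists passed.

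**Figure D3:**
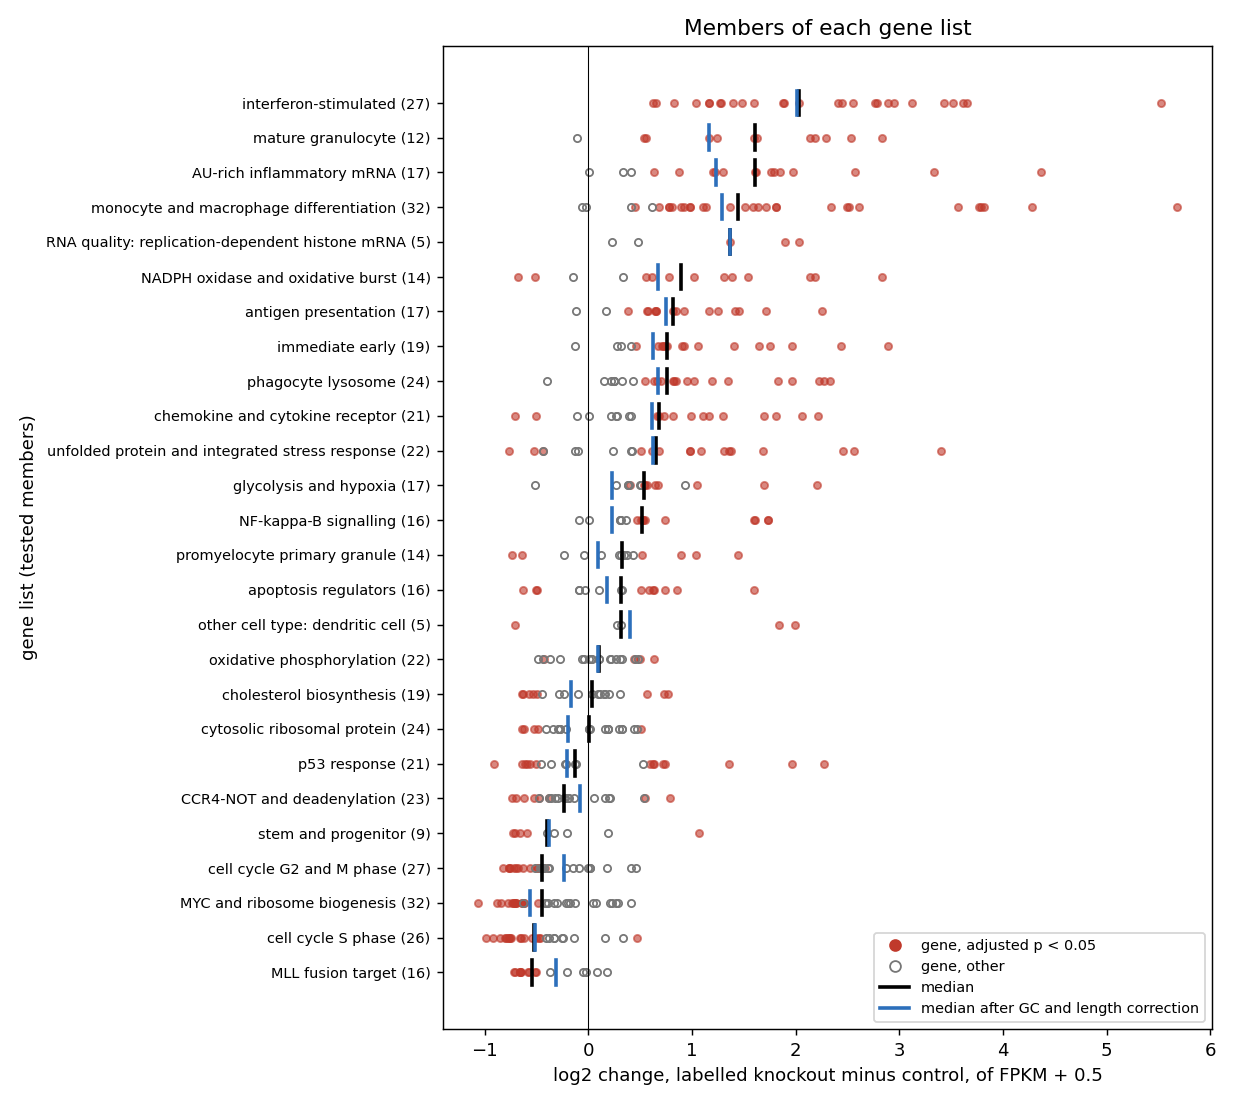
Log2 change of every tested member of the gene lists, libraries labelled knockout against control; each point is 1 gene, filled where its adjusted p is under 0.05, and bars show the list's median before and after correction for GC content and length. The interferon-stimulated list has the highest median among the lists fixed before the data were examined with at least 5 tested members, 2.03, and the MLL fusion target list the lowest, -0.54.

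Each guide alone was compared with the same 3 controls, which asks whether both guides change the same genes. With guide 3, CD14 rose by 6.22 ± 0.29 on the log2 scale (adjusted p = 4.2e-07), IFI6 by 5.29 and FCN1 by 5.06, while SHISA2 (-2.48), IGSF10 (-1.71) and CHML (-1.68) fell most. With guide 5, IFI6 rose by 5.77 ± 0.19 (adjusted p = 1.9e-07), CD14 by 5.13 and CCL2 by 4.32, and SHISA2 (-1.97), the pseudogene EIF4BP7 (-1.66) and NOL5BP (-2.08) fell most. ZFP36L2 mRNA was higher with guide 3, 1.91 ± 0.20 (adjusted p = 6.6e-05), and with guide 5, 1.12 ± 0.20 (adjusted p = 0.0035). Guide 3 gave 1593 risen and 1166 fallen genes, and guide 5 gave 841 and 503. The counts with guide 3 were 606 and 112 without guide 3 replicate 2 and 895 and 305 without its replicate 1, and 761 fell without control replicate 1. Those with guide 5 were 325 and 28 without guide 5 replicate 1, 471 and 55 without its replicate 2, and 560 and 173 without control replicate 1. The fallen genes with guide 5 were 804 and 998 without control replicates 2 and 3, 179 and 181 without guide 3 replicates 1 and 2, and 1154 after correction for GC content and length.

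Across genes, which are not independent replicates, the log2 changes of both guides had a Pearson r of 0.897, against 0.400 ± 0.0128 (SD over 100 simulations) for unchanged groups that share the 3 control libraries. Of the tested genes, 87.1% had the same sign with both guides, against 63.1% in these simulations. The simulations drew each gene independently and left out the GC trend along which the controls differed. Both values under no change could therefore be higher than simulated. With both guides 773 genes rose and 415 fell, and 1 gene was called in opposite directions; the shared controls add to this overlap, and no value for it under no change was computed. Of the 2865 genes called in the pooled comparison 2285 had the larger change with guide 3, and the median size of their log2 change was 0.79 with guide 3 and 0.59 with guide 5. The GC trend differed too: it spanned 1.12 and 1.55 on the log2 scale between the extreme bins in the guide 3 libraries and 1.03 and 0.52 in those of guide 5. Over all tested genes the SD of the log2 change was 0.738 with guide 3 and 0.603 with guide 5, and 0.569 and 0.529 after GC correction, where guide 3 gave 1109 risen and 1484 fallen genes and guide 5 gave 960 and 1154. The median of the interferon-stimulated list was 1.85 with guide 3 and 2.46 with guide 5, and that of the monocyte list 1.70 and 1.18. In the authors' deposited table, at a false discovery rate under 0.05, 2368 genes rose and 2236 fell with guide 3, and 1368 rose and 906 fell with guide 5. All 2759 limma calls with guide 3 and all 1344 with guide 5 had the same sign in the authors' deposited table, where 2665 and 1294 of them were also called.

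**Figure D4:**
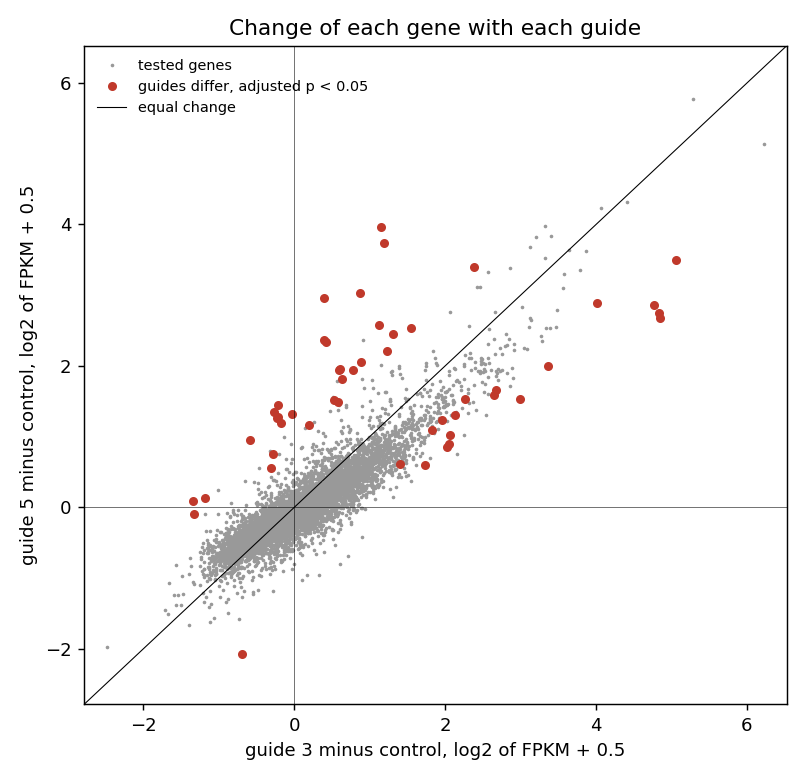
Log2 change against control with guide 3 (horizontal axis) and guide 5 (vertical axis); each point is 1 tested gene, in color where the guides differ, and the line marks equal change. The correlation across genes is 0.897, with DDIT4, STC2 and CHAC1 higher with guide 5 and S100A8, S100A9 and S100A12 higher with guide 3.

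The guides also differed from each other. Of the unfolded protein and integrated stress response list, DDIT4 was higher with guide 5, at 67.2 ± 5.84 FPKM against 9.26 ± 2.34 FPKM with guide 3 (SD, n = 2 each), a log2 difference of 2.81 ± 0.31 (adjusted p = 0.0018). STC2 (2.57) and CHAC1 (2.55) of the same list and ADM2 (2.16), a peptide hormone gene outside it, followed. The monocyte genes S100A9 (-2.17 ± 0.24, adjusted p = 0.0018), S100A12 (-2.09), S100A8 (-1.91) and FCN1 (-1.56) were lower with guide 5 than with guide 3, though all 4 rose against control with each guide. In all, 31 genes were higher and 19 lower with guide 5, 50 together, and this count depends strongly on the fit: 1228 genes differed with library weights, 774 with the guide libraries fitted alone, 196 with the replicate block, 100 after GC correction, 97 with no filter, 92 with quantile normalization and 9 with mean FPKM of at least 5. Without guide 5 replicate 2, 7 genes differed, and the adjusted p was 0.065 for FCN1, 0.062 for S100A8 and 0.055 for S100A9; without control replicate 2, 216 genes differed, and without guide 3 replicate 1, guide 3 replicate 2 and guide 5 replicate 1 it was 20, 19 and 13. With every library scaled to the same sum of FPKM, the adjusted p was 0.0574 for FCN1 and 0.122 for S100A12.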

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

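The tests of reads shared with paralogs and of genes of middle GC content were chosen only after the results were seen. The difference between the guides was itself tested, and 50 genes passed. Higher with guide 5 than with guide 3 were DDIT4 (2.81 on the log2 scale), STC2 (2.57), CHAC1 (2.55), ADM2 (2.16) and SESN2 (1.16). Lower with guide 5 were S100A9 (-2.17), S100A12 (-2.09), S100A8 (-1.91), FCN1 (-1.56) and NOL5BP (-1.39). With guide 5 replicate 2, guide 5 replicate 1, guide 3 replicate 2 or guide 3 replicate 1 left out 7, 13, 19 or 20 genes differed, and with control replicate 2 left out 216.

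The called genes of the pooled comparison followed GC content. Of 35 splits of the 7 libraries into 4 and 3, only the real one reached its count (2586 with a single mean for both guides). The highest other gave 1170, with both guide 3 libraries and guide 5 replicate 1 set against the rest. This rank is the most that 35 splits can show. Splits that mix the arms add the difference between arms to the spread within groups, so chance is not excluded. Libraries of 1 group differed along the same axis, with a Spearman rho across genes of 0.610 between GC content and their main deviation and of -0.298 for transcript length, so GC content may account for part of the calls, while length stays open. After correction 59.3% of the called genes were called in the same direction, which lies between the bounds set beforehand; for the 1165 no longer called in that direction, of which 7 were called in the opposite one, the median size of the log2 change went from 0.56 to 0.13, and the parts of the guides and of the trend stay open. Against GC content as the whole cause, 27.9% of tested genes of middle GC content passed (378 of 1357).

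All 27 tested interferon-stimulated genes, of 38 listed, rose, and the list had camera adjusted p = 2.2e-19 but adjusted p = 0.12 with an estimated correlation. The filter on FPKM can leave out members that stayed low, so this share covers tested members alone. A single library is argued against: at least 97.2% of the median log2 change was left with any 1 of the 7 libraries left out. After GC correction 99.3% was left. The members had a median GC content of 51.4%, in a bin with a median change of 0.06, so the correction could move their median little. The GC trend is argued against by size, as the list's median of 2.03 lay above the 0.61 of the bin with the most GC. That loss of ZFP36L2 may raise these mRNAs is a hypothesis that no test here decides, as the protein was not analysed here. A response to the guides or to DNA cleavage, which the non-targeting control would lack, stays open and was not tested, since no library had a guide that cuts elsewhere.

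ZFP36L2 mRNA was higher in the libraries labelled knockout. After the GC and length correction 83.2% of the log2 change was left (1.26, adjusted p = 0.00034), which argues against that trend as the cause. In 4 of 4 libraries the gain of 362 to 1025 CPM was above the total counted to ZFP36 and ZFP36L1, 213 to 298, which met the bound set against reads shared with them. Paralog reads assigned to ZFP36L2 would be in the gain and missing from that total, so this test cannot exclude shared reads. Edited transcripts that the protein no longer represses could be a biological explanation, which was not tested. An exchange of single libraries between arms would mix the arms. On the first principal component of all tested genes, the 3 controls lay at -40.8 to -18.5 and the other 4 libraries at 10.7 to 32.9. This argues against such an exchange, and arms of 3 and 4 libraries cannot be exchanged whole. Reads changed by editing stay open, as the sequence reads were not analysed here.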

How the results depend on the processing

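Recovered reads, voom, the GC correction, the authors' comparison and the left-out libraries of the AU-rich test were added only after the results were seen. Of 139 gene results, 126 kept direction and side of the threshold under GC correction, 131 with libraries scaled to the same sum, 135 under quantile normalization, and all 139 with other pseudocounts, no filter, library weights or voom. A smaller share than under GC correction was kept with guide 3 replicate 2 or guide 5 replicate 1 left out, which leaves 1 library with that guide. Reversed under GC correction were UQCRC1 (-0.00866), RPS2 (-0.16) and the length-matched AU-rich difference (0.0601, permutation p = 1e-05, the smallest possible); the cause of the sign change beyond the correction itself was not tested. The ZFP36L2 rise held under every setting run. No called list changed direction.

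Gene counts moved by over 1.5 times as follows; the cause was not tested except where a setting tests fewer genes or fits fewer samples. Mean FPKM of at least 5, which tests fewer genes, gave 557 risen and 342 fallen in the pooled comparison, 598 and 282 with guide 3, 283 and 158 with guide 5, 9 between guides, and 8 lists higher. Recovered CPM, which change both the measure and the genes tested, gave 2380 and 2347, 2414 and 2152, and 1393 and 876 in the same order. Voom on the same genes gave 2374 and 2418, 2502 and 2236, and 1452 and 951. Scaling to the same sum gave 2371 fallen pooled, 1026 risen and 2567 fallen with guide 3, and 940 fallen with guide 5. Quantile normalization gave 1825 fallen with guide 3, 1031 with guide 5, and 92 between guides. Library weights gave 1483 risen and 1126 fallen with guide 5 and 1228 between guides. GC correction gave 1154 fallen with guide 5 and 100 between guides. No filter gave 97 between guides. Fits of the compared groups alone, with fewer samples, gave 173 fallen with guide 5. Between guides such a fit gave 774, a higher count, which fewer samples do not account for. The controls, which take no part in the spread of that fit, deviated by -26.9 to 16.6 along the main deviation within groups, against -4.41 to 4.41 in the guide libraries. In the authors' deposited table, genes fallen with guide 3 numbered 2236, and 1368 rose and 906 fell with guide 5; it has no pooled comparison, so that alternative was not run. With an estimated correlation 0 lists were higher and 0 lower. The replicate block gave 1056 fallen with guide 5 and 196 between guides. Deviations with the same number correlated at 0.09, -0.13, -0.40, 0.44 and -0.57 across genes, with mixed signs. Control replicate 3 deviated together with guide 3 replicate 2 (0.60) and guide 5 replicate 1 (0.68). In groups of 2 libraries the deviations mirror each other, so these values cannot decide whether replicate numbers pair the libraries.

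With 1 library left out, where a lone sample is assumed to vary like the other groups, pooled counts ranged from 966 (without guide 3 replicate 2) to 1839 (without control replicate 2) risen and 559 (without guide 5 replicate 1) to 1701 (without control replicate 3) fallen. Guide 3 had 606 to 1979 risen and 112 to 1574 fallen, guide 5 had 325 to 1236 and 28 to 998, and 7 to 216 genes differed between guides. Throughout, 13 lists were higher and 4 lower. The correlation of guides ranged from 0.844 to 0.930, the ZFP36L2 change from 1.45 to 1.58, and the AU-rich difference from -0.0438 to -0.00819. Depth, at 16907955 to 38807816 reads, sets the value of a single read at 0.0261 to 0.0540 CPM; since FPKM are per kilobase of gene span, a low FPKM need not mean few reads, and no lower depth was tried.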

Other observations

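The heat shock list, its test, and the list tests of the guide difference were chosen only after the results were seen, and so were the GC-corrected and left-out-library values of the AU-rich test. Of 26 tested members of the heat shock list, 14 fell and 1 rose in the libraries labelled knockout. Their median log2 change was -0.73 (GC-corrected -0.56). HSPH1 (-1.37), HSP90AA1 (-1.23), CHORDC1 (-1.21), HSPA8 (-1.18) and BAG2 prompted the test. In the 21 other members, which include HSPE1 (-1.15), DNAJA1 (-1.08) and HSPD1 (-1.06), the median was -0.34 (GC-corrected -0.49), with 9 fallen and 1 risen (camera p = 0.0015, p = 0.12 with an estimated correlation). HSPD1 was already named among the falls of the MYC and ribosome biogenesis list, so these members were not all unseen before the test. Not past the threshold were, among others, HSPA1B (-0.18, adjusted p = 0.38), DNAJB1 (-0.31, adjusted p = 0.10), BAG3 (0.23, adjusted p = 0.12) and HSPB1 (0.44, adjusted p = 0.14). HSPA1B was at 0.28 with guide 3 and at -0.65 with guide 5. After GC correction HSPA1B (-0.65, adjusted p = 0.0043) and DNAJB1 (-0.51, adjusted p = 0.0019) were lower, while BAG3 (-0.16, adjusted p = 0.057) and HSPB1 (-0.31, adjusted p = 0.073) did not pass. Lower expression of this list as a group is a candidate explanation that the preset test favors and the estimated correlation leaves open. It did not hold for every member.

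Between the guides, genes of the unfolded protein and integrated stress response had a median 0.66 higher with guide 5 on the log2 scale (GC-corrected 0.66, camera adjusted p = 1.3e-16, adjusted p = 0.018 with an estimated correlation). DDIT4, STC2, CHAC1 and SESN2 prompted this test; in the 18 other members the median was 0.50 (camera adjusted p = 1.8e-08, adjusted p = 0.064 with an estimated correlation), so a difference of the list beyond the genes seen first stays open. Other lists passed camera at the preset correlation too, of which a part is given here, and none of them passed with an estimated correlation. Interferon-stimulated genes had a median difference of 0.54, guide 5 minus guide 3 (GC-corrected 0.57, camera adjusted p = 3.8e-18, adjusted p = 0.17 with an estimated correlation). That of G2 and M phase genes was 0.37 (GC-corrected 0.33, camera adjusted p = 7.1e-08, adjusted p = 0.48 with an estimated correlation). That of mature granulocyte genes was -0.54 (GC-corrected -0.44, camera adjusted p = 7.1e-06, adjusted p = 0.27 with an estimated correlation). Monocyte genes had a median difference of -0.47 (GC-corrected -0.47, camera adjusted p = 4.1e-11, adjusted p = 0.20 with an estimated correlation; -0.45, 1.3e-06 and 0.28 without S100A9, S100A12, S100A8 and FCN1) and cholesterol biosynthesis genes of -0.45 (GC-corrected -0.38, camera adjusted p = 1.2e-06, adjusted p = 0.064 with an estimated correlation).

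If ZFP36L2 destabilizes mRNAs with AU-rich elements, mRNAs with the heptamer in their 3′ UTR could rise when it is lost. Among 6363 genes, the 1938 with a heptamer had a median log2 change of -0.18 and the others 0.08, a difference of -0.261, which met the bound written beforehand against the hypothesis. Within bins of 3′ UTR length the mean difference was -0.0230 (permutation p = 0.0258), and medians for 0, 1, 2 and 3 or more heptamers were 0.08, -0.15, -0.20 and -0.27. The question is left open because that bound took no account of GC content, and this choice was made after the values were seen: the correction changed the difference of medians by 147% of its size, to medians of -0.01 with and -0.13 without a heptamer. The length-matched difference then turned to 0.0601 (permutation p = 1e-05, the smallest possible). Without correction the permutation p was 0.0965, 0.415, 0.0749 and 0.169 with control replicate 1, control replicate 2, guide 3 replicate 2 and guide 5 replicate 1 left out, and genes are not independent replicates.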
